A study of Mus musculus with 16 samples.

How the data were processed

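The series measured chromatin of immortalized mouse embryonic fibroblasts by chromatin immunoprecipitation followed by sequencing (ChIP-seq). Both lines carried a doxycycline-inducible Cre recombinase, and either both copies of Sdhc or 1 copy of Sdhc was flanked by loxP sites. Per the labels' protocols, doxycycline was given at 1 µg/mL, cells were collected at day 16 and fixed with formaldehyde, and chromatin was cut with micrococcal nuclease and sonicated. Libraries came from input chromatin or from chromatin bound by antibodies to succinyllysine, H3K4me3 or H3K27me3, with 2 samples per line and antibody.

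The authors deposited 1 list of regions per antibody, and the values in these lists are start and end positions on mm10 with no height, score or value per sample. Per the submitters' processing notes, reads were aligned with Bowtie2 version 2.2.3 to the mm10 build. The peak caller, its threshold, the use of the input libraries, and whether the 4 ChIP libraries of an antibody were pooled, merged or compared are not given in the sources used here. In all 3 lists every start ended in 01 and every end in 00, so positions were read as 1-based and inclusive on a grid of 100 bp. Each list is a single observation. The lists give no read depth, and neither the input libraries nor the difference between the lines was analysed here.

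Genes were the 21887 protein-coding genes of a RefSeq gene table for GRCm38.p6, which has the coordinates of mm10. That table gives the outer ends of each gene without strand, exons or sequence. The planned promoter window around each transcription start was therefore replaced by windows of 1000 bp on each side of both gene ends, and the planned exon and intron classes by gene end, gene body and intergenic. A gene carried a mark when a region shared at least 1 bp with either window. Starts inside a gene were missed by this rule. Of 9724 genes without H3K4me3 at an end, 1258 (12.9%) had an H3K4me3 region inside the gene. Without annotated starts, it is not known how many of these regions lay at a start. Chromosome length was taken as the span from the lowest to the highest coordinate of any region or gene, and runs of unknown sequence were not left out.

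Overlap between 2 lists was the share of regions with at least 1 bp in common with the other list. It was compared with 1000 random placements of the same regions, with their widths, on their own chromosome. The two-sided permutation p has 0.002 as the smallest value that 1000 placements can give. Region midpoints were assigned to the annotation classes and compared with placements in the same way. Genes were compared with two-sided Fisher's exact tests, and shares carry exact Clopper-Pearson 95% intervals. P-values and intervals cover counting error only, since the deposited lists hold no values per sample, and neighbouring genes and regions are not independent.

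The design, the 26 gene lists and the alternatives were fixed before the data were examined. Each list was tested against all other protein-coding genes for each mark, and the 78 p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. All names of 24 lists were found in the gene table. The list of imprinted genes matched 21 genes from 26 names, several of which are noncoding genes. The histone list had been written under both current and older names and matched 41 genes from 75 names. Named genes followed a rule: the 4 Sdh subunit genes, the 5 genes at the widest region of each antibody, and up to 4 members of each list per histone mark state, taken by the width of the succinyllysine region, then of the H3K4me3 and the H3K27me3 region. Genes named outside this rule are pointed out where they occur. Some genes that the rule names are not reported here.

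Alternatives were windows of 500 and 2500 bp, an overlap of at least 50% of the placed region or of its midpoint, regions wider than the median of their list, autosomes alone, circular shifts of a list, placement within 10000 bp of gene ends, largest overlap in place of the midpoint, merging of regions within 1000 bp, and H3K4me3-marked genes as background. Added after the data were seen were whole genes with 1000 bp on each side, removal of regions that touched both other lists, and rotation of the marks along the order of genes, which keeps neighbouring genes together. The use of every annotated start and a background chosen by CpG content need an annotation and a genome that were not used here.

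The procedures were tested on simulated data. Of 20 randomly placed lists of 10888 regions, 1 gave p under 0.05 for overlap with H3K4me3, and shares set by construction were recovered within 0.055 percentage points. The random lists came from the same placement as the test itself, so they check the calculation alone. In 50 simulations over 21887 genes, with succinyllysine raised 5-fold in 8 lists, 73.5% of the raised lists were called. Of the tests of H3K4me3 and H3K27me3, for which no list was raised, 0.308% were called. Marks were drawn independently for each gene, so this rate does not cover lists whose neighbouring genes share regions. False succinyllysine calls in the unchanged lists were not counted. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with matplotlib 3.10.9 for figures.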

Results

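ChIP-seq libraries were made from 2 lines of immortalized mouse embryonic fibroblasts, in which doxycycline turns on a Cre recombinase that removes floxed Sdhc. Sdhc encodes a membrane anchor of succinate dehydrogenase, the enzyme of the tricarboxylic acid cycle that oxidises succinate to fumarate. The experimental line had 2 floxed copies of Sdhc (fl/fl) and the control line had 1 floxed and 1 wild-type copy (fl/wt). At day 16 of doxycycline, each line gave 2 samples of input chromatin and 2 samples each with antibodies to succinyllysine (lysine carrying a succinyl group), H3K4me3 (a histone mark of active promoters) and H3K27me3 (a mark of Polycomb-repressed chromatin), 16 samples in all. The deposited lists gave 1 set of regions per antibody for its 4 ChIP samples, so fl/fl and fl/wt cells could not be compared, and whether a region was marked in 1 line or in both is not given in the sources used here. Read depth is unknown for all samples. The comparisons that follow ask where the succinyllysine regions lay in these cells relative to the other 2 marks and to genes.

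The succinyllysine list held 10888 regions covering 7.50 Mb, with a median width of 300 bp and a widest region of 27800 bp. H3K4me3 had 26654 regions covering 50.4 Mb (median 1100 bp), and H3K27me3 had 98342 regions covering 88.4 Mb (median 600 bp). The widest H3K4me3 region (31100 bp, chromosome 2, 74668001 to 74699100, mm10) covered Hoxd10, Hoxd11, Hoxd12 and Hoxd13 and reached into Hoxd9, homeobox genes that pattern limbs and the body axis. The widest H3K27me3 region (98000 bp, chromosome 15, 102901201 to 102999200) ran over genes including Hoxc10, Hoxc11, Hoxc12 and Hoxc13 and reached Hoxc6. The widest succinyllysine regions at gene ends lay at Zfp982, a zinc finger gene in a cluster where other succinyllysine regions touched both other lists (14700 bp, chromosome 4, 147517001 to 147531700), and at the shared end of Ugt1a1, Ugt1a2, Ugt1a5 and Ugt1a10, which encode UDP-glucuronosyltransferases (14000 bp, chromosome 1, 88211201 to 88225200). H3K4me3 regions of 13500 bp and 13800 bp overlapped these 2 succinyllysine regions.

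Succinyllysine lay on H3K4me3 regions far more often than random placement gave. Of the 10888 succinyllysine regions, 1840 touched an H3K4me3 region, 16.9% (95% exact CI 16.2 to 17.6) against 2.73% under placement (6.19-fold, permutation p = 0.002, the smallest possible). At Cdkn1b, an inhibitor of cyclin-dependent kinases, an 8200 bp succinyllysine region lay within a 10300 bp H3K4me3 region. At Actb, which encodes cytoplasmic actin, a 3600 bp succinyllysine region (chromosome 5, 142906801 to 142910400) overlapped in part with a 5500 bp H3K4me3 region (142902701 to 142908200). The overlap depended on width: 3.39% of the 4657 regions of 200 bp touched H3K4me3 (1.51-fold), 7.10% of the 3141 regions of 300 to 500 bp did (2.98-fold), and 46.5% of the 1097 regions of 600 to 1000 bp did (16.4-fold). Of regions of 1100 to 2000 bp 49.4% touched H3K4me3, and of those over 2000 bp 44.9%. Seen from the other list, 6.33% of the H3K4me3 regions touched succinyllysine.

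The relation of succinyllysine to H3K27me3 changed direction with width. Over all regions 6.06% touched H3K27me3 (CI 5.62 to 6.53), against 5.40% under placement (1.12-fold, permutation p = 0.002). The excess came from narrow regions, at 1.32-fold for 200 bp and 1.88-fold for 300 to 500 bp. Regions of 1100 to 2000 bp touched H3K27me3 less often than placed ones (1.16% against 7.41%, 0.156-fold, permutation p = 0.002), as did those over 2000 bp (5.24% against 10.4%, 0.503-fold, permutation p = 0.002). With circular shifts of the list the overall excess did not pass (permutation p = 0.106), and it turned to a deficit of 0.584-fold with placement near gene ends and of 0.460-fold for regions wider than the median. Between the histone marks, 4.29% of H3K4me3 regions touched H3K27me3 against 7.34% under placement (0.584-fold, permutation p = 0.002). This relation also changed direction with width, though not steadily. H3K4me3 regions of 200 bp had a small deficit (0.873-fold, permutation p = 0.036). Those of 300 to 500 bp (1.45-fold, permutation p = 0.002) and 600 to 1000 bp (1.20-fold, permutation p = 0.008) had an excess. Those of 1100 to 2000 bp did not differ from placement (0.966-fold, permutation p = 0.619), and those over 2000 bp had a deficit (0.174-fold, permutation p = 0.002).

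**Figure D1:**
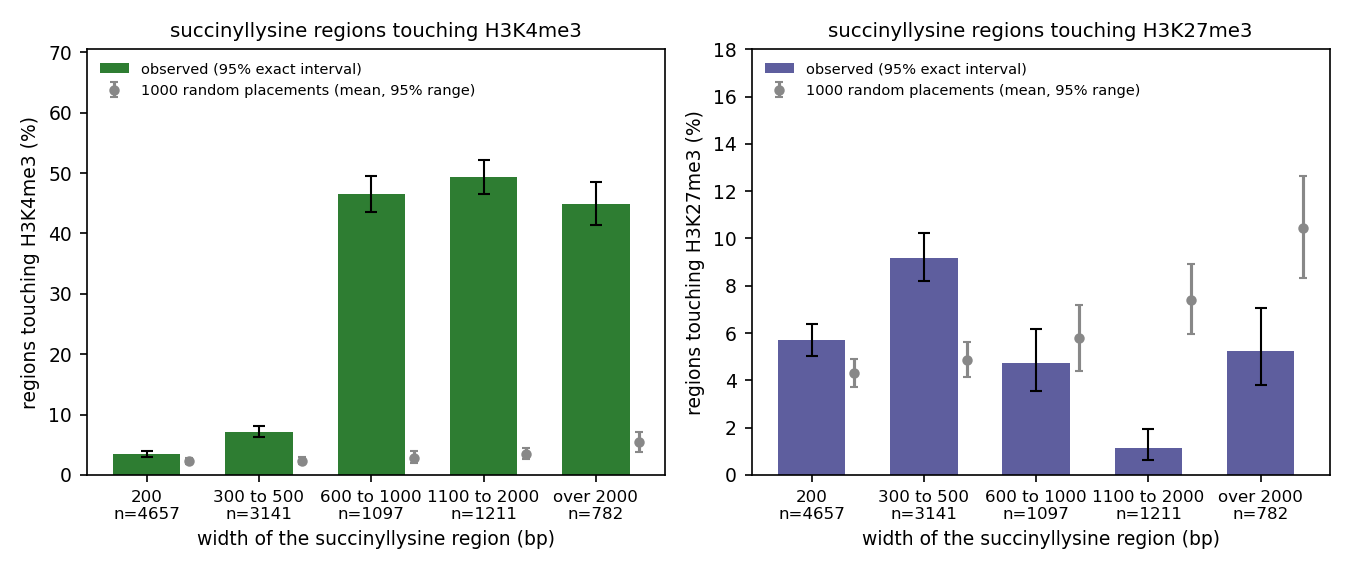
Share of succinyllysine regions (%, bars with 95% exact intervals) that touched H3K4me3 (left) or H3K27me3 (right) by width of the succinyllysine region in bp, with the mean and 95% range of 1000 random placements as grey points. Overlap with H3K4me3 was 46.5% at 600 to 1000 bp against 3.39% at 200 bp, while regions of 1100 to 2000 bp lay below placement for H3K27me3 (1.16% against 7.41%).

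Gene ends held 7.88% of succinyllysine midpoints, 2.54-fold the share under placement (permutation p = 0.002). For H3K4me3 that share was 28.2% (8.98-fold, permutation p = 0.002), and for H3K27me3 3.25% (1.03-fold, permutation p = 0.05), which did not pass with largest overlap in place of the midpoint (permutation p = 0.152). Most succinyllysine regions were intergenic (63.1%, 1.09-fold), and gene bodies held 29.0% (0.749-fold), both with permutation p = 0.002. The intergenic excess belonged to narrow regions, since regions wider than the median gave 0.854-fold.

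Of the 21887 protein-coding genes, 1187 (5.42%) had succinyllysine at a gene end, 12163 (55.6%) had H3K4me3 and 2971 (13.6%) had H3K27me3. Succinyllysine occurred at 8.46% of genes with H3K4me3 (CI 7.97 to 8.97) and at 1.62% of genes without it (odds ratio 5.60, Fisher's exact p = 1.02e-123). It occurred at 1.68% of genes with H3K27me3 (CI 1.25 to 2.21) and at 6.01% of those without (odds ratio 0.268, Fisher's exact p = 4.94e-28). Among 10486 genes with H3K4me3 at exactly 1 end, succinyllysine lay only at the H3K4me3 end in 711 genes and only at the other end in 40 (exact binomial p = 8.08e-160). H3K27me3 also lay more often at the H3K4me3 end of these genes, in 317 only there and in 161 only at the other end (exact binomial p = 8.50e-13).

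Genes with both histone marks carried succinyllysine less often than genes with H3K4me3 alone, at 23 of 684 genes (3.36%, CI 2.14 to 5.00) against 1006 of 11479 (8.76%, CI 8.25 to 9.30; odds ratio 0.362, Fisher's exact p = 5.76e-08). The 2 marks could lie at different ends of a gene, so the group with both is not limited to ends where they meet. Examples with both marks and no succinyllysine at the ends were Hoxb6, Hoxb7 and Hoxb8 within a 54000 bp H3K27me3 region, the stem cell factor Sox2, and Epas1, which encodes HIF-2α. Genes with H3K27me3 alone had succinyllysine in 27 of 2287 cases (1.18%) and genes with neither mark in 131 of 7437 (1.76%), a difference that did not pass (odds ratio 0.666, Fisher's exact p = 0.0583). When whole genes with 1000 bp on each side were used, the relation to H3K27me3 turned to an odds ratio of 1.46, and that of genes with both marks to 2.53. A whole-gene window grows with gene length, which gives every mark more room, and length was not adjusted for. The turned values therefore cannot be read as a relation between the marks.

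**Figure D2:**
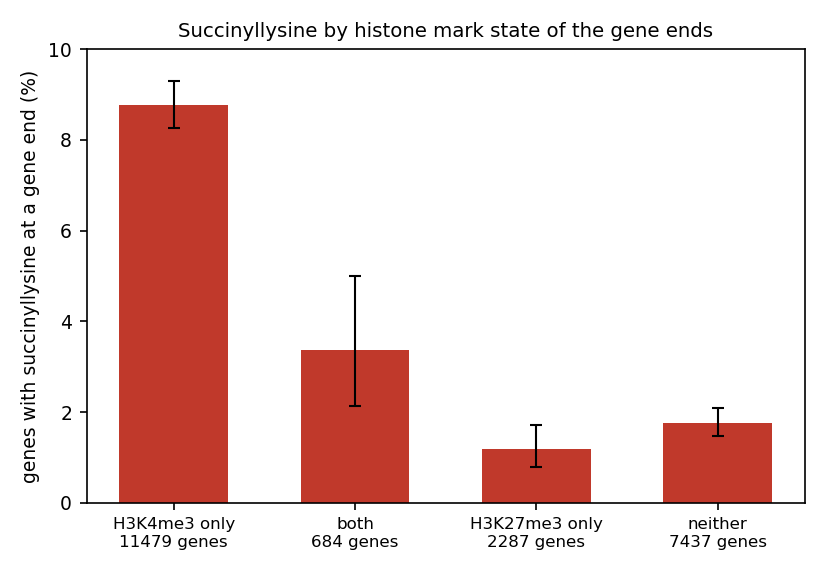
Share of protein-coding genes (%, y axis) with a succinyllysine region within 1000 bp of a gene end, by whether the ends carried H3K4me3 only, both histone marks, H3K27me3 only or neither, with 95% exact intervals as error bars. The share was 8.76% with H3K4me3 only and 3.36% with both marks, which could lie at different ends of a gene.

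Of 26 gene lists, 8 carried succinyllysine at gene ends more often than other genes, at adjusted p under 0.05. The other 18 did not pass (Fisher's exact test with Benjamini-Hochberg adjustment). No list was called lower, but lists of up to 55 genes were too small for such a call. Of 55 developmental transcription factors 0 were marked, with adjusted exact p = 0.117. Immediate-early and growth response genes had the highest share, 13 of 29 (44.8%, CI 26.4 to 64.3) against 5.37% of other genes (adjusted exact p = 1.29e-08). They included Nr4a1, a nuclear receptor (5600 bp, chromosome 15, 101248501 to 101254100), the antiproliferative gene Btg2 (3800 bp), and Fosl2 and Fos, which encode subunits of the AP-1 transcription factor (3400 bp and 2900 bp). Fibroblast and extracellular matrix genes followed with 12 of 30 (40.0%, adjusted exact p = 1.66e-07). Among them were S100a4, a fibroblast calcium-binding protein (8000 bp), Col6a1 and Col6a2, which encode collagen VI chains (7100 bp and 4500 bp), and Loxl1, a crosslinker of elastin (4500 bp). Succinyllysine at Col6a1 (chromosome 10, 76726201 to 76733300) began where the 2600 bp H3K4me3 region at the gene's end stopped.

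Replication-dependent histone genes carried succinyllysine in 16 of 41 cases (39.0%, adjusted exact p = 2.25e-09), through 13 regions because neighbouring genes share some. Examples were H4c14 (1900 bp), H2bc3 (1600 bp), and H2ac4 and H2bc6 (1000 bp each). Of 22 contractile cytoskeleton and actin genes 8 were marked (36.4%, adjusted exact p = 4.38e-05), including Actb (3600 bp), the actin-binding profilin gene Pfn1 (2800 bp), and Tagln2 and the tropomyosin gene Tpm4 (2200 bp each). Of 39 Hox genes 8 were marked (20.5%, adjusted exact p = 0.00311), among them Hoxa9 and Hoxa10, which shared a 5000 bp region on chromosome 6 (52228301 to 52233300), Hoxa11 and Hoxd13 (4600 bp each), and Hoxd11 (3100 bp). All 8 were among the 16 Hox genes with H3K4me3 alone, and none were among the 11 with both histone marks or the 12 with H3K27me3 alone. These 5 lists also passed among H3K4me3-marked genes alone, where the share was 46.4% of immediate-early genes, 44.4% of fibroblast genes, 39.0% of histone genes, 38.1% of contractile genes and 29.6% of Hox genes, with adjusted p from 1.48e-06 to 0.00660. Hox and histone genes lie in clusters, so their members are not independent in these exact tests. Rotation of marks along the order of all genes gave weaker adjusted p of 0.0395 for Hox genes and 0.0031 for histone genes. For immediate-early, fibroblast and contractile genes it was 0.000396 each. Rotation was not run among H3K4me3-marked genes alone.

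The other 3 higher lists did not pass among H3K4me3-marked genes. Cytosolic ribosomal protein genes had 11 of 77 marked (14.3%, adjusted exact p = 0.00819, and 0.296 among H3K4me3-marked genes), with Rpl10 (1500 bp), Rpl13a and Rpsa (1300 bp each) and Rpl27a (1100 bp). The list of INK4-ARF, p53 targets and senescence had 4 of 19 marked (21.1%, adjusted exact p = 0.0338, and 0.145 among H3K4me3-marked genes). Its 4 marked genes were the kinase inhibitors Cdkn1b (8200 bp) and Cdkn2a (1700 bp), and the tumour suppressor Trp53 and its apoptotic target Bax (1100 bp each). Spliceosome and RNA processing genes had 5 of 32 marked (15.6%, adjusted exact p = 0.0480, and 0.522 among H3K4me3-marked genes), including Hnrnpu and Snrpc (1300 bp each), Sf3a2 (1000 bp) and Snrpa (800 bp). At Bax and Hnrnpu the succinyllysine region lay at the opposite gene end from the widest H3K4me3 region. With marks rotated along the gene order, the adjusted p was 0.0665 for the INK4-ARF list and 0.0940 for the spliceosome list. The INK4-ARF list also did not pass with windows of 500 bp (adjusted exact p = 0.0934), windows of 2500 bp (0.0598) or whole genes (0.0613), nor the spliceosome list with windows of 500 bp (0.0979), autosomal genes alone (0.0542) or whole genes (0.481), nor the ribosomal list over whole genes (0.180).

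**Figure D3:**
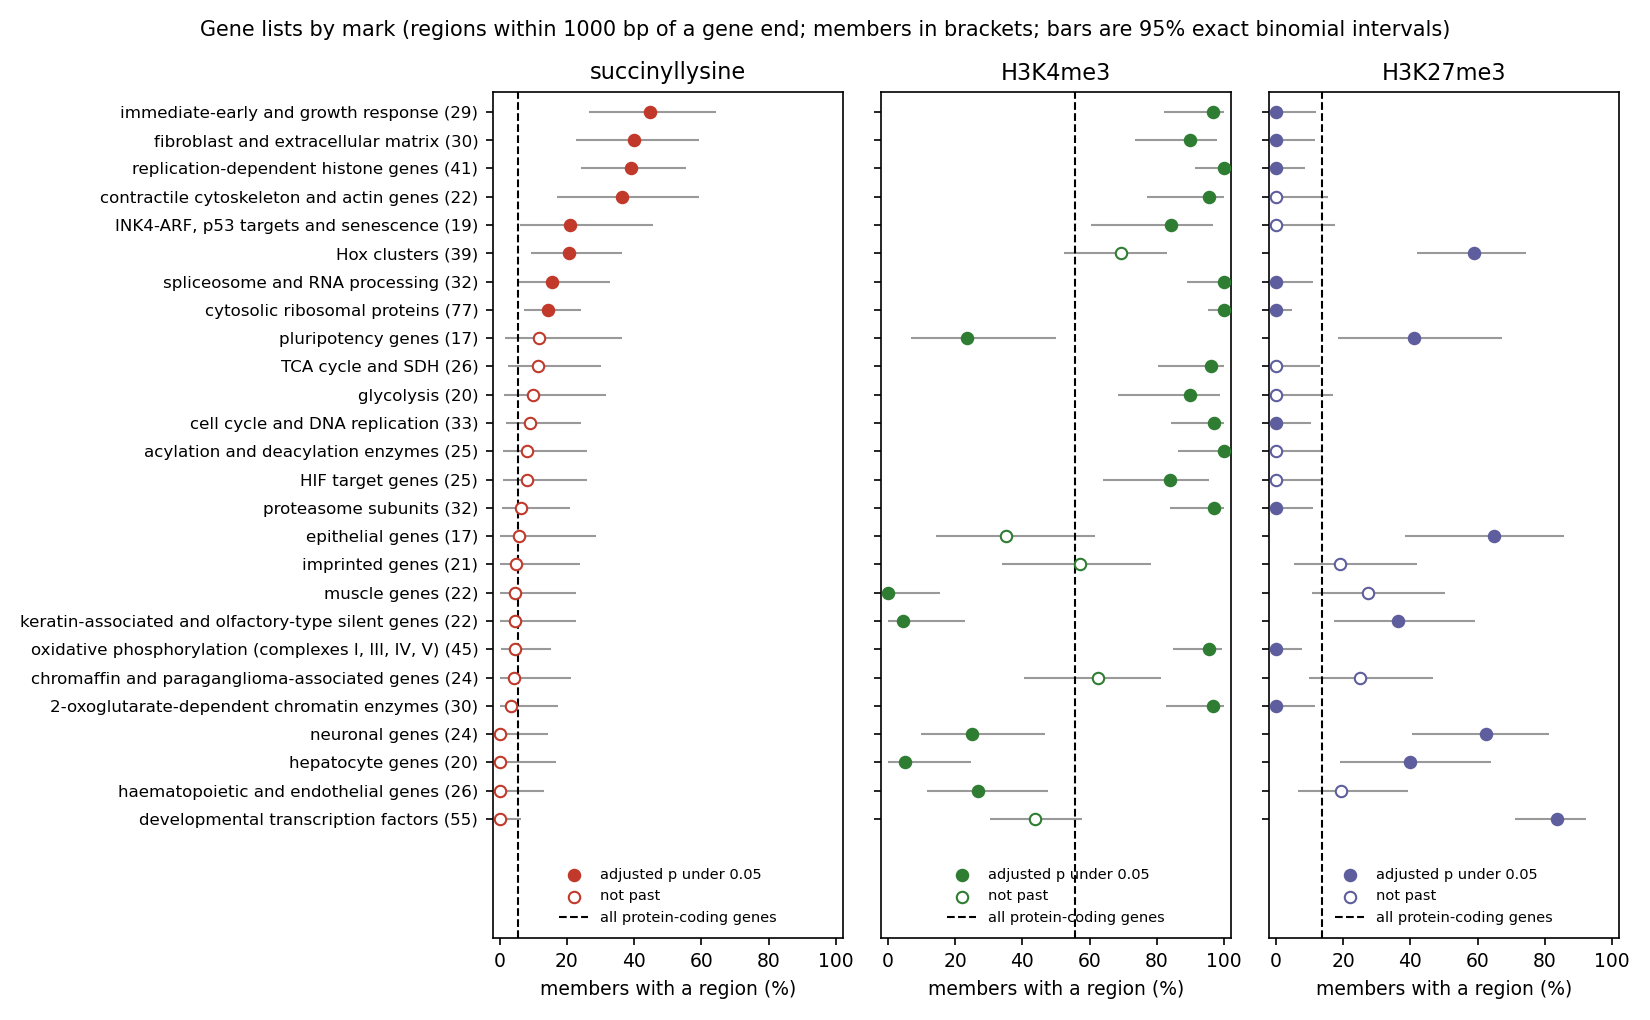
Share of each list's members (%, x axis) with a region of succinyllysine, H3K4me3 or H3K27me3 within 1000 bp of a gene end, with 95% exact intervals. Filled points passed adjusted p under 0.05 and the dashed line is the share of all protein-coding genes. Immediate-early genes stood at 44.8% for succinyllysine against 5.42% of all genes.

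Among the 4 subunit genes of succinate dehydrogenase, succinyllysine was listed at Sdhc alone. Sdhc (chromosome 1, 171129157 to 171150640) had a 900 bp succinyllysine region (171150601 to 171151500) at its upper end, inside a 4000 bp H3K4me3 region. Sdha, Sdhb and Sdhd had H3K4me3 regions of 5400, 3300 and 5200 bp at a gene end and no succinyllysine. Of the 26 genes for the tricarboxylic acid cycle and succinate dehydrogenase, 3 were marked (11.5%, CI 2.45 to 30.2, adjusted exact p = 0.222), namely Sdhc, Dld and Pdha1, with regions of 900, 500 and 400 bp. Oxidative phosphorylation genes had 2 of 45 marked (4.44%), Atp5g1 and Atp5g2, which encode ATP synthase subunit c. Glycolysis genes had 2 of 20 (Aldoa and Eno2), and HIF target genes had 2 of 25 (Lox and Ankrd37).

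Of 30 2-oxoglutarate-dependent chromatin enzymes, whose activity succinate can inhibit, Kdm5a was marked (1100 bp), a share of 3.33%, and of 25 acylation and deacylation enzymes Kat5 (1300 bp) and Sirt6 (1000 bp) were, a share of 8%, beside 5.42% of all genes. Proteasome subunits had 2 of 32 marked (Psma3 and Psmc2), and cell cycle and DNA replication genes 3 of 33 (Cdk4, Cdt1 and Mcm5). Pluripotency genes had 2 of 17 marked (Klf2 and Klf4, both also on the immediate-early list), and imprinted genes 1 of 21 (Grb10). A single gene was marked in the lists of 22 muscle genes (Tnni2, 5800 bp), 17 epithelial genes (Krt8), 22 keratin-associated and olfactory-type genes (Defb1) and 24 chromaffin and paraganglioma-associated genes (Sdhc). No member was marked among 55 developmental transcription factors (CI up to 6.49%), 26 haematopoietic and endothelial genes, 24 neuronal genes or 20 hepatocyte genes. None of these 18 lists passed for succinyllysine, with adjusted p from 0.117 to 1.

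H3K4me3 was more frequent than in other genes in 15 lists and less frequent in 6. It marked all 77 ribosomal protein genes, 41 histone genes, 32 spliceosome genes and 25 acylation enzymes. It marked 43 of 45 oxidative phosphorylation genes, 32 of 33 cell cycle genes, 31 of 32 proteasome genes, 29 of 30 2-oxoglutarate-dependent enzymes, 28 of 29 immediate-early genes, 27 of 30 fibroblast genes, 25 of 26 tricarboxylic acid cycle genes, 21 of 25 HIF targets, 21 of 22 contractile genes, 18 of 20 glycolysis genes and 16 of 19 genes of the INK4-ARF list. The lower lists were muscle (0 of 22), hepatocyte (1 of 20), keratin-associated and olfactory-type (1 of 22), pluripotency (4 of 17), neuronal (6 of 24) and haematopoietic and endothelial genes (7 of 26). The pluripotency list did not pass for H3K4me3 with regions wider than the median (adjusted exact p = 0.0503) or over whole genes (0.0669). Some genes without H3K4me3 at their outer ends carried it inside, such as Ldha (3600 bp, chromosome 7, 46844701 to 46848300) and Cdkn1a (2300 bp, chromosome 17, 29093301 to 29095600).

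H3K27me3 was more frequent in 7 lists. Developmental transcription factors led with 46 of 55 (83.6%, CI 71.2 to 92.2, adjusted exact p = 1.32e-29), among them Sox1 (39000 bp), Pax7 (35200 bp), Otx2 (27900 bp) and Pax2 (26100 bp). The others were epithelial genes (11 of 17, with 24300 bp at the splicing regulator Esrp1), neuronal genes (15 of 24, with 18100 bp at the vesicular GABA transporter gene Slc32a1), Hox genes (23 of 39), pluripotency genes (7 of 17, with 7100 bp at Lin28a), hepatocyte genes (8 of 20, with 3500 bp at Alb, which encodes albumin) and keratin-associated and olfactory-type genes (8 of 22). Over whole genes the pluripotency list did not pass for H3K27me3 (adjusted exact p = 0.0906). No H3K27me3 region was listed at the gene ends of 15 lists, of which 9 were called lower, namely ribosomal, oxidative phosphorylation, histone, cell cycle, proteasome, spliceosome, fibroblast, immediate-early and 2-oxoglutarate-dependent enzyme genes. The other 6, which did not pass, were tricarboxylic acid cycle, glycolysis, HIF target, acylation enzyme, contractile and INK4-ARF genes. Since none of the 15 lists had a marked member, the calls followed list size. The 9 lists had 29 to 77 members and the 6 had 19 to 26. For the 77 ribosomal protein genes the exact interval reached 4.68%. Of those 9 calls, 3 passed with windows of 500 bp and 2 with regions wider than the median, and with windows of 2500 bp the 2-oxoglutarate-dependent enzymes did not pass (adjusted exact p = 0.0724). With marks rotated along the gene order 6 passed, and the adjusted rotation p was 0.140 for histone genes and 0.0543 for both immediate-early and fibroblast genes. Chromaffin genes had 6 of 24 with H3K27me3 and did not pass for a difference from other genes (adjusted exact p = 0.176).

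**Figure D4:**
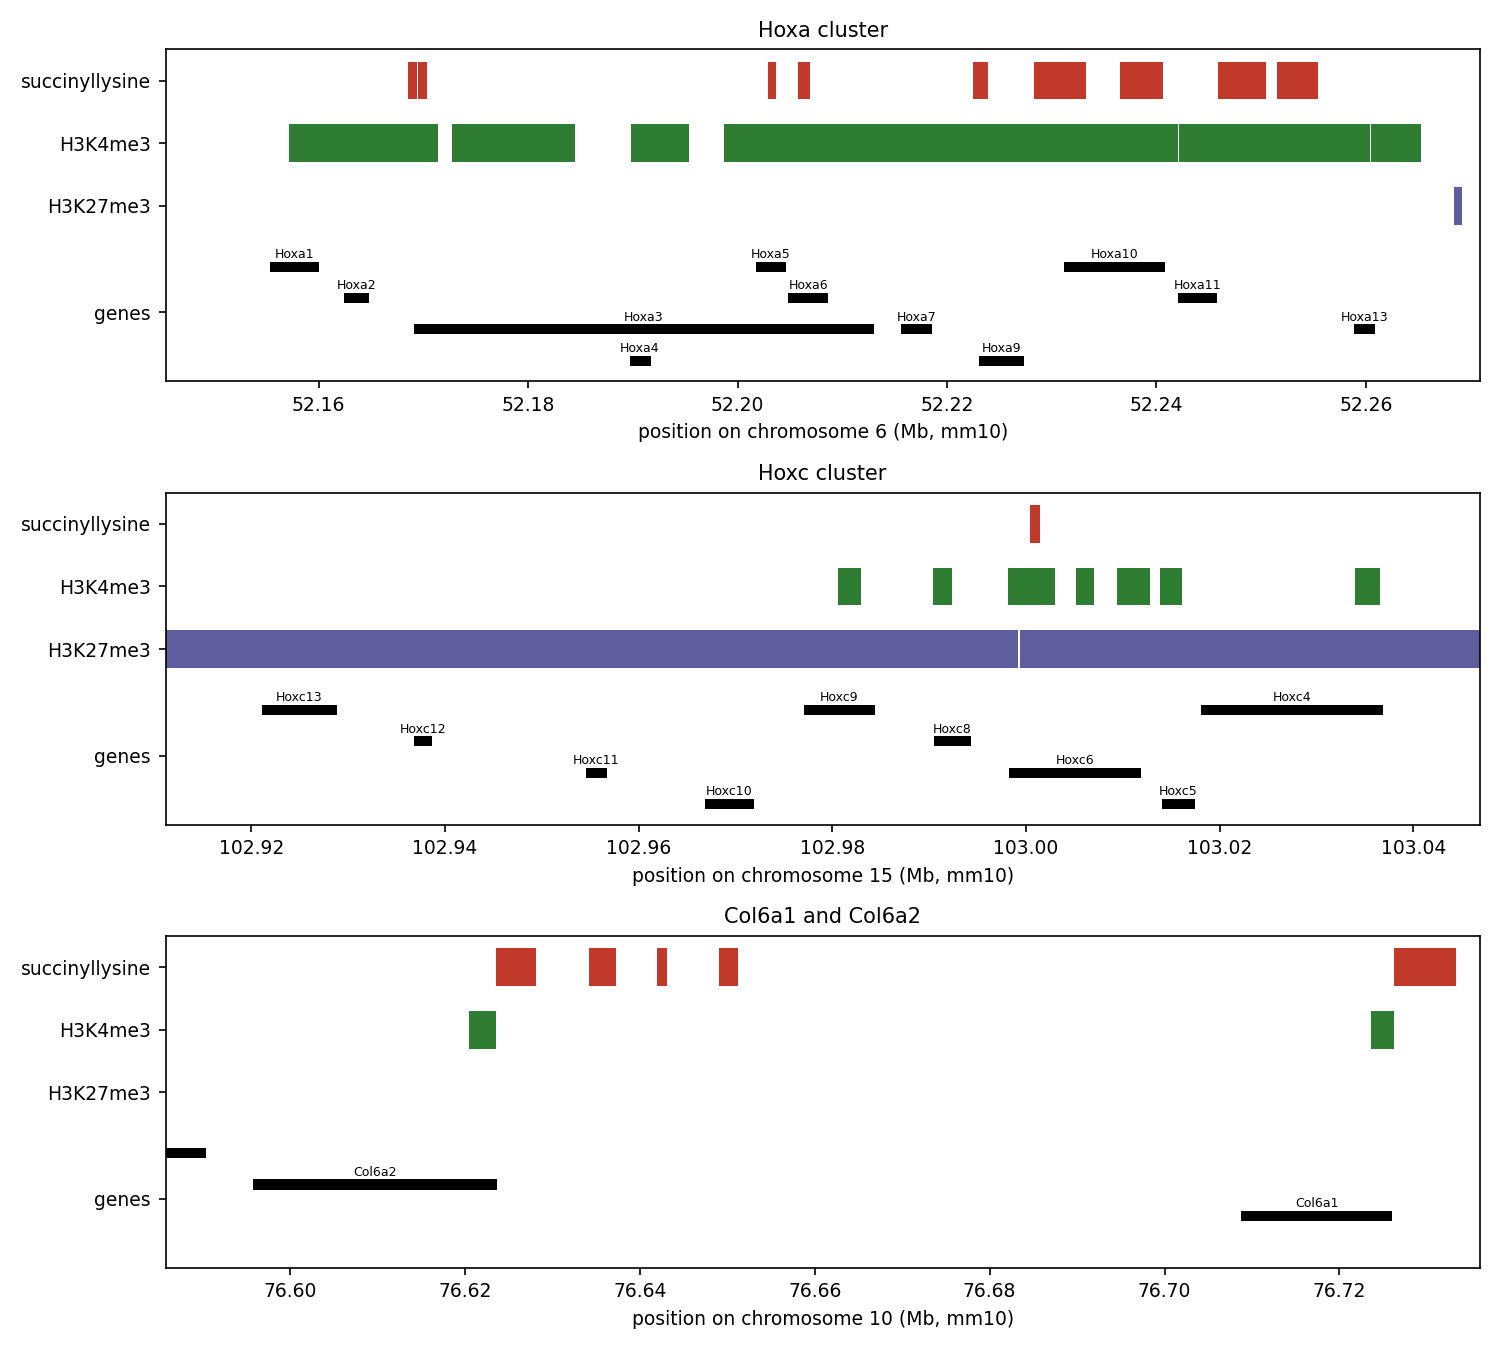
Maps of the Hoxa cluster (chromosome 6), the Hoxc cluster (chromosome 15) and the Col6a1 and Col6a2 genes (chromosome 10), with position in Mb on mm10 along x and regions of each list and gene extents as bars. The Hoxa window held 9 succinyllysine regions, H3K4me3 over most of the cluster and 1 H3K27me3 region of 800 bp, whereas H3K27me3 covered 135526 bp of the Hoxc window, which held 1 succinyllysine region of 1000 bp.

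Windows reached 10000 bp beyond the outermost genes of a cluster. In the Hoxa window (chromosome 6, 52145367 to 52270880) 9 succinyllysine regions summed to 22600 bp and 10 H3K4me3 regions to 98000 bp. In the Hoxc window (chromosome 15, 102911131 to 103046856) H3K27me3 regions covered 135526 bp, 8 H3K4me3 regions to 19400 bp, and the single succinyllysine region measured 1000 bp. No test was run between clusters.

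The X chromosome carried fewer regions per Mb than the autosomes in each list. It held 66 succinyllysine regions, 0.386 per Mb against 4.43 per Mb on autosomes (ratio 0.0872, CI 0.0674 to 0.111). The ratio was 0.366 for H3K4me3 (CI 0.339 to 0.396) and 0.554 for H3K27me3 (CI 0.536 to 0.573). Among genes with H3K4me3, succinyllysine was present at 8.08% of 359 X-linked genes (CI 5.48 to 11.4) and at 8.47% of 11800 autosomal genes (Fisher's exact p = 0.923). The marked X-linked genes included Rpl10 (1500 bp) and Pdha1 (400 bp), which encodes a subunit of pyruvate dehydrogenase.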

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

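Whole genes, removal of regions touching both other lists, and rotation along the gene order were chosen after the data were seen. No paired analysis was possible because the lists hold no values per sample. For the same reason, comparisons between fl/fl and fl/wt cells, with the block, other count tests, filters, pseudocounts and each replicate left out, were not run, nor were a background by CpG content and the use of every annotated start. The overlap of succinyllysine with H3K4me3 kept its direction and its side of the threshold under all 7 alternatives, from 4.40-fold to 11.5-fold, and that of H3K4me3 with H3K27me3 from 0.374-fold to 0.906-fold. The overlap of succinyllysine with H3K27me3 (1.12-fold) was 0.460-fold for regions wider than the median and 0.584-fold with placement near gene ends. It did not pass with circular shifts (1.12-fold, permutation p = 0.106). Without regions touching both other lists it was 0.884-fold, but a fall was set by construction, since every removed succinyllysine region touched H3K27me3. With regions wider than the median, intergenic shares turned to 0.854-fold for succinyllysine and 0.987-fold for H3K27me3, the gene body share to 1.21-fold for H3K4me3, and the H3K27me3 gene body share did not pass (1.00-fold). The H3K4me3 gene body share was 1.06-fold by largest overlap and passed at 0.581-fold with windows of 2500 bp, and the H3K27me3 gene end share did not pass by largest overlap (1.02-fold). Over whole genes, the odds ratio of succinyllysine turned to 1.46 by H3K27me3 and to 2.53 for both marks against H3K4me3 alone. Whole-gene windows grow with gene length for every mark, and length was not adjusted for, so these 2 values cannot decide on a relation between marks. Windows of 500 and 2500 bp left the directions found at gene ends in place. Merging gave 52031 H3K27me3 regions. For succinyllysine, 5 lists were higher over whole genes and 5 against H3K4me3-marked genes, in place of 8. For H3K27me3, 3 lists were lower with windows of 500 bp, 2 with regions wider than the median and 14 over whole genes, in place of 9. The causes were not tested. Of other single lists and named genes under alternatives, 916 results were the same, 32 lost a call, 20 moved and none reversed. A named gene could only stay the same or move. The restriction to regions wider than the median left all 215 named genes the same by construction, since no listed succinyllysine region at them was as narrow as the median. The unknown depth limits every list, since a segment that is not listed may have been too thinly covered to be called.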

Other observations

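The comparisons for gene number and for an equal loss on X were chosen after the results were seen. So were the tests of segments shared by all lists, of regions beside H3K4me3 and of neighbouring regions counted once. The other tests were set down before their results were seen, and the 5 gene lists tested below were those that passed among H3K4me3-marked genes.

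Many wide succinyllysine regions lay away from gene ends and H3K4me3. Of 1993 regions over 1000 bp, 897 (45.0%) touched no H3K4me3 region and lay over 2500 bp from every gene end. The widest was 18200 bp (chromosome 7, 142469201 to 142487400), with Lsp1 as the nearest gene, and others of 10700 bp and 9900 bp lay 104 and 93.0 kb from Cebpb, which encodes a transcription factor. These genes, and the members named in the next paragraph, were chosen after their values were seen. Of the 1993 wide regions, 127 (6.37%) lay beside an H3K4me3 region, within 1000 bp of it and without touching, as at Col6a1, against 1.78% under placement (3.57-fold, permutation p = 0.002). Those placements ran over the whole chromosome, while 949 of the wide regions (47.6%) touched H3K4me3. The excess therefore cannot tell a position beside H3K4me3 from general closeness to it.

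If the distal wide regions followed only the positions of H3K4me3-marked genes, their share near the 5 lists would equal that of random placements within 100 kb of such genes. Of the 713 that lay within that reach, 8.56% had a member of the 5 lists within 100 kb, against 1.64% of placed regions (5.23-fold, permutation p = 0.002, the smallest possible). The 5 lists had been chosen for succinyllysine at their gene ends in the same data, and that choice favoured further succinyllysine around them. Placed regions could also fall on gene ends and H3K4me3 regions, where the 713 could not. The test therefore shows an excess near these lists but cannot decide on position alone. Among the 713 regions the excess lay near immediate-early genes (7.82-fold), fibroblast genes (5.92-fold) and contractile genes (3.36-fold, adjusted permutation p = 0.0173 each), such as Cebpb with 6 regions, Col5a1 with 5, and Ier2 and Myh9 with 4 each, while Hox and histone genes had 0 regions where placement gave 0.145% and 0.0498%, too few to tell a difference. With chains of neighbouring regions counted once, the 5 lists together kept a 4.53-fold excess over 384 regions (permutation p = 0.002). No single list passed, at 6.14-fold for immediate-early genes, 4.46-fold for fibroblast genes (adjusted permutation p = 0.0519 each) and 4.46-fold for contractile genes (0.0693). Immediate-early genes had the smallest possible p before adjustment (permutation p = 0.002). A list alone at that smallest p was adjusted to 0.0519, so it could not pass whatever its excess. For immediate-early genes, the chain test therefore cannot tell whether the excess was lost. A hypothesis is that these regions may be distal regulatory elements of genes active in fibroblasts, which would need RNA of the neighbouring genes and a mark of active enhancers in these cells to decide, and input reads over the same regions to set it against reads drawn by open chromatin, none of which was analysed here.

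Regions shared by succinyllysine and H3K27me3 may be segments that draw reads with any antibody. Among succinyllysine regions of up to 500 bp, 12.5% of the 553 that touched H3K27me3 also touched H3K4me3, against 4.31% of the other 7245 (odds ratio 3.17, Fisher's exact p = 1.32e-13), as such segments would give. In addition, 113 regions had identical start and end in both lists, while the highest of 100 placements was 10, and 12 were identical in all 3 lists. Regions touching both other lists lay at gene ends less often than those touching H3K4me3 alone (9.09% against 50.7%, odds ratio 0.0971). That comparison weighs little, since H3K27me3 midpoints were rarer at gene ends in general (3.25% against 28.2% for H3K4me3). Of the 143 regions touching both other lists, 13 lay at gene ends. This argues against promoters carrying both histone marks, at the gene ends used here, as the source of most of these regions. The widest lay among the clustered Zfp993, Zfp982 and Chil4 genes, of which Zfp993 and Chil4 were chosen after their values were seen, the first of these regions measuring 9500 bp, so reads from near-identical copies remain an untested candidate source.

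Succinyllysine was scarcest on X among narrow regions over 2500 bp from gene ends, with 21 on X and 7425 on autosomes. Their density ratio was 0.0404 (CI 0.0250 to 0.0618). This ratio is the pattern itself, so it cannot decide whether fewer H3K4me3-marked genes on X were the cause. The ratio of such narrow H3K4me3 regions was 2.75 times as high, and that of H3K27me3 was 0.983. For regions over 500 bp away from gene ends, the ratio was 0.103 for succinyllysine (CI 0.0563 to 0.174) and 0.308 for H3K4me3. For H3K27me3 it was 0.150 (CI 0.136 to 0.164), an interval that overlapped that of succinyllysine. Counts of listed narrow regions on X thus differed between marks. They cannot decide on an equal loss of signal, since depth is unknown and a weaker signal may be listed as narrower regions or not at all. Coverage that differs between chromosomes also remains open. Across the 19 autosomes, the density of narrow succinyllysine regions away from gene ends gave a Spearman rho of 0.258 with that of H3K27me3 (r = 0.297, permutation p = 0.287 and 0.219, adjusted over 2 relations 0.287 and 0.219, and r = 0.401 without the 2 farthest autosomes). With that of H3K4me3 the rho was 0.872 (r = 0.831, permutation p = 1e-05 and 3.00e-05, adjusted 2.00e-05 and 6.00e-05, and r = 0.786 without 2). No biological explanation was tested.

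Of H3K4me3 regions near gene ends, 12.1% of those of 4000 bp or more touched succinyllysine against 5.81% of those of 1200 to 2600 bp, but the fold over placement was only 1.04 times as high (4.71 against 4.54), while regions of 2700 to 3900 bp had a lower fold of 3.19 and those of 200 to 1100 bp, of which 3.66% touched, had a fold of 4.72. Whether succinyllysine preferred wide H3K4me3 regions beyond the effect of width was left open by this test.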
